A study of Homo sapiens with 6 samples.

How the data were processed

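RNA was measured in 6 libraries of MCF10A cells, an immortalised human mammary epithelial line: 3 from a line stably expressing the fluorescent protein mCherry and 3 from a line stably co-expressing HA-tagged flotillin 1 and mCherry-tagged flotillin 2. Per the labels' protocols, the libraries came from a stranded mRNA kit and were sequenced on a HiSeq instrument. The flotillin line had been infected with 2 retroviral vectors and selected with puromycin and hygromycin, and the control line with 1 vector and puromycin, per the labels' protocols. Samples were grouped by the titles in the labels, 3 per group. Nothing in the labels says that the 3 samples of a group came from separate cultures, so p-values measure the spread between these samples, which may be technical.

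The authors deposited 2 tables of the same comparison, each with 52401 genes, of which 52313 have the same identifier in both. HISAT2 2.1.0, HTSeq 0.9.1, DESeq2 1.18.1, bcl2fastq and build GRCh37 are named in the submitters' processing notes; the annotation release is not given in the sources used here. The first deposited table holds 2 columns of signal, the mean of the size-factor-normalized read counts of each group, as their values show. It also holds the authors' log2 fold change of flotillin over control, whose median size is 0.963 times the log2 ratio of the 2 means, as in a moderated estimate. Its p-values and adjusted p-values are the authors' own, per the file headers, and 19733 genes have an adjusted p. The second table comes from the Tuxedo pipeline per its name, and the authors' group values in it are in FPKM, per the file headers. Its log2 fold changes, test score and q-values are also the authors', per the file headers, with 17022 genes marked as tested and a smallest p of 5e-05. Aligner and versions of that pipeline are not given in the sources used here. Gene positions are those of its locus column in GRCh37, counted from 1, and a locus can join neighbouring or overlapping genes.

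The signal columns are group means, but each mean was deposited with 15 significant digits. A mean of 3 libraries is the sum of 3 whole read counts, each divided by 3 times its size factor, so the steps between low values give the size factors and a search over whole numbers gives the reads. A single solution was found for 99.72% of the control means above 0 and 99.71% of the flotillin means above 0. Altered means, tried as a check, had a solution in 0.05% and 0.0% of 2000 cases per group. Size factors recomputed from the solved counts differed from the fitted ones by at most 0.028%. On simulated reads the search returned 100.0% of 3000 genes per group exactly. The altered means and the simulated reads left out the highest means. They therefore do not cover genes such as DSG3, CDH1 and SAA1 in the control group. The 107 genes without a single solution in both groups all have a group mean above 18335 and hold 22.0% of the control and 20.3% of the flotillin normalized counts; for these only the authors' group means are given. The recovered libraries carry no replicate numbers and are called library 1 to 3 within each group, in order of falling size factor. Standard deviations below are over the 3 recovered libraries of a group.

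The solved genes hold between 18591665 and 19714482 reads per library.

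Genes that rose or fell are those with an adjusted p under 0.05 in the authors' deposited table of means, which is the main result. The design fixed before the data were examined named a test on counts for the case that whole reads could be recovered. That test was not run, a departure from the design, because the columns hold group means and 107 genes with high group means have no recovered reads. In its place a second fit ran limma 3.58.1 (R 4.3.3, trend and robust options, Benjamini-Hochberg adjustment) on log2(normalized count + 1) of the recovered libraries for the 15904 solved genes with a mean of at least 10. Data were simulated for this comparison over those 15904 genes with a dispersion of 0.0512, each gene drawn independently. In them the fit called 64% of 100 genes changed 2-fold and 100% of 100 genes changed 4-fold, and 5.75% of its calls were false. These rates do not cover differences that many genes of a library share. Tables were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and numba 0.67.0, and figures with matplotlib 3.10.9.

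29 gene lists were fixed before the data were examined: flotillins, caveolae and stomatin family; EMT transcription factors; mesenchymal markers; epithelial junction and polarity genes; basal and luminal mammary markers; keratinocyte differentiation; receptor tyrosine kinases; ERK targets; TGF-beta genes; matrix proteases; integrins; collagens and laminins; sphingolipid genes; endosome and lysosome genes; RAS and PI3K genes; interferon-stimulated, NF-kB, cell cycle, p53, unfolded protein, cholesterol, hypoxia, stem cell, mitochondrial and housekeeping genes; and fibroblast, immune and endothelial markers. Symbols were matched by gene identifier or by the tables' own symbols, and of the entries CD24 and PECAM1 had no match. Each list was tested with limma's cameraPR at a preset inter-gene correlation of 0.01 on the signed statistic of the authors' p-values, with the 19733 tested genes as background and Benjamini-Hochberg adjustment over the 29 lists. Beside it stand camera with an estimated correlation and fry, both on the recovered libraries. The estimated correlation rests on only 3 libraries per group and takes in differences that genes of a library share. A list that does not pass with it may still have moved. On random statistics for 19733 genes, cameraPR called 99% of lists of 20 genes moved by 1 and 5% of unmoved lists. These statistics were drawn independently, so the rates do not hold for lists whose genes vary together.

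Genes named in the text follow a rule fixed at the same time: FLOT1, FLOT2, CDH1, CDH2, VIM, ZEB1, ZEB2 and AXL whatever their values; the 10 largest rises and 10 largest falls among genes past adjusted p 0.05 with a mean of at least 100 normalized counts and groups that do not overlap; and per list up to 4 members past adjusted p 0.05 with the largest changes and a mean of at least 100, or 20 where none reaches it. Genes without recovered reads in 1 or both groups, such as FN1 and CADM3, were kept without the check for overlap. The rule gave 117 genes. Alternatives covered the Tuxedo table, limma-voom, filters on low counts, thresholds, Bonferroni adjustment, centring, pseudocounts, leaving out each library and variants of the set tests. Chosen after seeing the data were the limma fit itself, total-count scaling, fits without library 3 of both groups or with a term for it, the removal of genes with unexplained zeros, set tests without FLOT1 and FLOT2, and 5 further gene lists.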

Results

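Gene expression was compared between MCF10A cells carrying mCherry and MCF10A cells with raised flotillin 1 and flotillin 2, 3 libraries per group. Flotillins are scaffold proteins of membrane microdomains and endocytic vesicles, and MCF10A is a non-tumorigenic breast epithelial line with basal features. Each library held between 18591665 and 19714482 reads in the genes whose counts could be recovered. The comparison asks how the transcriptome of these cells differs when both flotillins are raised together.

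The introduced genes were higher in the flotillin line. FLOT1 (chromosome 6, 30695486 to 30710510) rose from 1475 ± 380 to 16771 ± 2432 normalized counts (SD, n = 3), 11.4-fold. FLOT2 (chromosome 17, 27206353 to 27224715) rose 11-fold, from an authors' mean of 3727 to one of 41052. In the authors' deposited table the log2 fold changes were 3.38 (adjusted p = 1.03e-32) for FLOT1 and 3.35 (adjusted p = 5.14e-35) for FLOT2. Gene-level counts do not separate the endogenous transcripts from the introduced ones.

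Flotillin cells held far fewer transcripts of several epithelial adhesion genes and more of several mesenchymal ones. CDH1, which encodes the epithelial adhesion protein E-cadherin (chromosome 16, 68771128 to 68869444), fell 223-fold, from 17575 ± 2685 to 78.9 ± 36.7 normalized counts (SD, n = 3). CDH2, the gene of N-cadherin, rose 3.49-fold, from 625 ± 200 to 2182 ± 436 (SD, n = 3). FN1, encoding the matrix protein fibronectin, rose 28.0-fold between the authors' means, from 5648 to 157920, and VIM, encoding the intermediate filament vimentin, rose 3.67-fold, from 8337 to 30572. ZEB1 and ZEB2, repressors of CDH1, rose 5.83-fold and 4.97-fold, to 909 ± 208 and 749 ± 115 normalized counts (SD, n = 3). The receptor tyrosine kinase gene AXL lay at 3669 ± 1090 in control and 4332 ± 1090 in flotillin libraries (SD, n = 3), and the authors' deposited table gives it a log2 fold change of 0.23 with an adjusted p of 0.638. For CDH1, CDH2, VIM, ZEB1 and ZEB2 the authors' deposited table gives log2 fold changes of -7.31, 1.72, 1.82, 2.45 and 2.24, with adjusted p-values of 3.13e-90, 1.69e-06, 2.12e-11, 1.38e-16 and 1.36e-16.

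**Figure D1:**
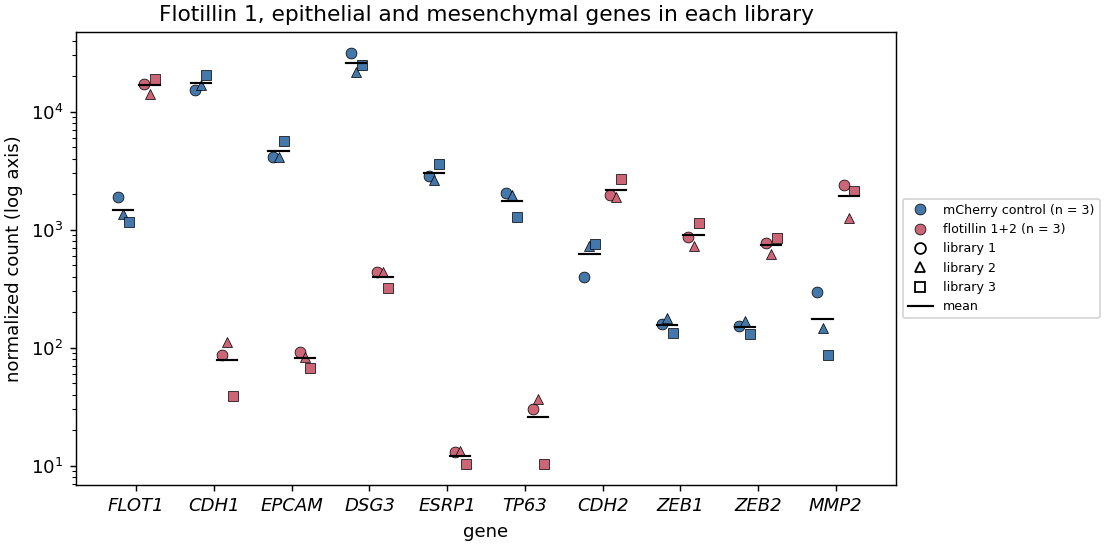
Normalized counts (log axis) of 10 genes in each of the 3 control and 3 flotillin libraries, with the group mean as a bar. The groups do not overlap for any of these genes: FLOT1, CDH2, ZEB1, ZEB2 and MMP2 are higher in the flotillin libraries, and CDH1, EPCAM, DSG3, ESRP1 and TP63 are lower.

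Across the genome, 4661 of 19733 tested genes (23.6%) passed an adjusted p of 0.05 in the authors' deposited table, 2298 higher and 2363 lower in flotillin cells. Large changes were mostly falls: 240 genes fell and 63 rose by a log2 fold change of at least 3 in the authors' deposited table. The median log2 fold change of the 11463 tested genes with a mean of at least 100 was 0.11 in the authors' deposited table. The limma fit of the recovered libraries called 3716 of 15904 genes, and 3685 of them were among the 4391 deposited calls in that fit, in the same direction. Without library 3 of both groups, which stood apart in cell cycle genes (below), limma called 7032 genes; this alternative was chosen after seeing the data, and 4241 deposited calls were among them in the same direction. Each group is a single stable line made with its own vectors and drugs, so flotillin level, vector number and hygromycin selection cannot be told apart.

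CDH1 was 1 of the 10 largest falls. FXYD3, a small membrane protein gene, went from 4297 ± 2064 to 12.8 ± 2.2 normalized counts, and ESRP1, an epithelial splicing regulator, from 3026 ± 505 to 12.2 ± 1.6 (SD, n = 3). LAD1, an anchoring filament protein gene, fell from 1991 ± 1048 to 6.75 ± 0.51, and BDKRB2, the bradykinin B2 receptor gene, from 1872 ± 239 to 11.2 ± 3.8 (SD, n = 3). FUT3, a fucosyltransferase gene with close paralogs, stood at 616 ± 95.5 in control and 1.01 ± 1.01 in flotillin libraries (SD, n = 3). The list of the 10 largest falls was completed by B3GNT3, FGFR3, CAMK2B and AP1M2 with log2 fold changes of -6.91, -6.22, -6.20 and -6.14 in the authors' deposited table.

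Among the 10 largest rises was ARMCX3, an X-linked gene of a mitochondrial outer membrane protein, which went from 15.5 ± 2.2 to 659 ± 53.1 normalized counts (SD, n = 3). FMN2, an actin nucleator gene, went from 6.10 ± 2.18 to 279 ± 16.1, and ABCA8, a lipid transporter gene, from 13.5 ± 8.3 to 462 ± 137 (SD, n = 3). FRMD3 rose 21.7-fold and ATOH8 17.1-fold between the group means. CTGF, a matricellular gene, rose 16.5-fold, from 197 ± 43.2 to 3254 ± 661 (SD, n = 3), and CADM3, a cell adhesion gene, rose 20.4-fold. The transcript CTA-134P22.2, which shares its locus with CADM3, rose 18.9-fold, and its reads are uncertain where the 2 overlap. In the authors' deposited table the log2 fold changes of these rises ran from 3.75 for CTA-134P22.2 to 5.17 for ARMCX3.

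Of 37 tested junction and polarity genes, 29 fell (31 adjusted over the list alone; set test adjusted p = 4.63e-74, limma cameraPR). With an estimated correlation the adjusted p was 0.335. The desmosomal cadherin gene DSG3 fell from 26115 ± 4977 to 399 ± 66.8 normalized counts, and EPCAM, an epithelial adhesion gene, from 4608 ± 865 to 81.0 ± 12.9 (SD, n = 3). Among 17 basal mammary markers 12 fell (12 adjusted over the list alone, with 1 rise, set test adjusted p = 7.11e-17). The set test with an estimated correlation (adjusted p = 0.335) covered only the 10 basal markers in the limma fit. That fit called 4 falls, and limma without library 3 of both groups 5 falls and 1 rise. TP63, the basal lineage transcription factor, fell 69.0-fold, and the nerve growth factor receptor gene NGFR went from 319 ± 230 to 3.05 ± 2.06 normalized counts (SD, n = 3). The hemidesmosomal collagen gene COL17A1 fell 33.2-fold between the authors' means. The keratin gene KRT15 had an authors' mean of 26875 in control and 735 ± 753 normalized counts in flotillin libraries (SD, n = 3). Luminal markers gave 4 falls among 14 tested genes (5 adjusted over the list alone; adjusted p = 0.00163, and adjusted p = 0.519 with an estimated correlation), among them ERBB3 (6.38-fold) and the protease inhibitor gene SLPI, which went from 9983 ± 3164 to 2010 ± 1078 normalized counts (SD, n = 3). ELF3, an epithelial transcription factor, fell 91.3-fold, and the authors' deposited table from the Tuxedo pipeline gives it a q-value of 0.328. Of 22 keratinocyte differentiation genes 16 fell (16 adjusted over the list alone; adjusted p = 9.03e-09, and adjusted p = 0.335 with an estimated correlation). The Tuxedo table called 4 falls in this list, with a set test adjusted p of 0.000821 (cameraPR). Limma called 14 falls with all libraries, 14 with a term for library 3 and 9 without library 3 of both groups. The calprotectin subunit gene S100A8 went from 5048 ± 2996 to 424 ± 376, the transglutaminase gene TGM1 from 1601 ± 1067 to 167 ± 86.8 and the kallikrein gene KLK7 from 394 ± 388 to 1.35 ± 0.58 normalized counts (SD, n = 3). Stem cell and subtype markers had 4 falls among 10 tested genes (5 adjusted over the list alone, set test adjusted p = 0.00163). With an estimated correlation, over the 6 members in the limma fit, the adjusted p was 0.356. Falls included CD44 (2.20-fold) and ALDH1A3, at 1541 ± 1340 in control and 112 ± 24.5 in flotillin libraries (SD, n = 3).

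On the mesenchymal side the lists were mixed. Of 19 tested mesenchymal markers 8 rose and 3 fell (the same 8 and 3 when counted adjusted over the list alone; adjusted p = 0.00121 for a rise, and adjusted p = 0.519 with an estimated correlation). For a rise the adjusted p was 0.0775 with ranks, 0.148 on the limma fit and 0.305 in limma without library 3 of both groups. Beside FN1, the gelatinase gene MMP2 rose from 176 ± 109 to 1921 ± 592, the fibrillin gene FBN1 from 261 ± 19.4 to 2545 ± 1848 and S100A4 from 1176 ± 559 to 5541 ± 2586 normalized counts (SD, n = 3). COL1A1, the type I collagen gene, fell 3.05-fold. EMT transcription factor genes gave 5 rises and 2 falls among 14 tested (6 and 2 adjusted over the list alone; adjusted p = 0.00419, and adjusted p = 0.335 with an estimated correlation). FOXC2 rose 4.13-fold, while SOX9 fell from 267 ± 258 to 28.4 ± 4.8 normalized counts (SD, n = 3). In the list of flotillins, caveolae and stomatins, 5 of 13 rose (6 adjusted over the list alone; adjusted p = 2.19e-05, and adjusted p = 0.519 with an estimated correlation). FLOT1 and FLOT2, the introduced genes, are 2 of these 5, and without them the list did not pass (adjusted p = 0.0614, a test added after seeing the data). PTRF, the caveolar coat gene cavin 1, rose 2.77-fold. Fibroblast markers, a check for other cells, had 3 rises and 2 falls among 9 tested (3 and 2 adjusted over the list alone; adjusted p = 0.198), with COL1A1 lower and DCN, encoding decorin, higher, from 4659 ± 3082 in control libraries (SD, n = 3) to an authors' mean of 42467 in flotillin cells.

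**Figure D2:**
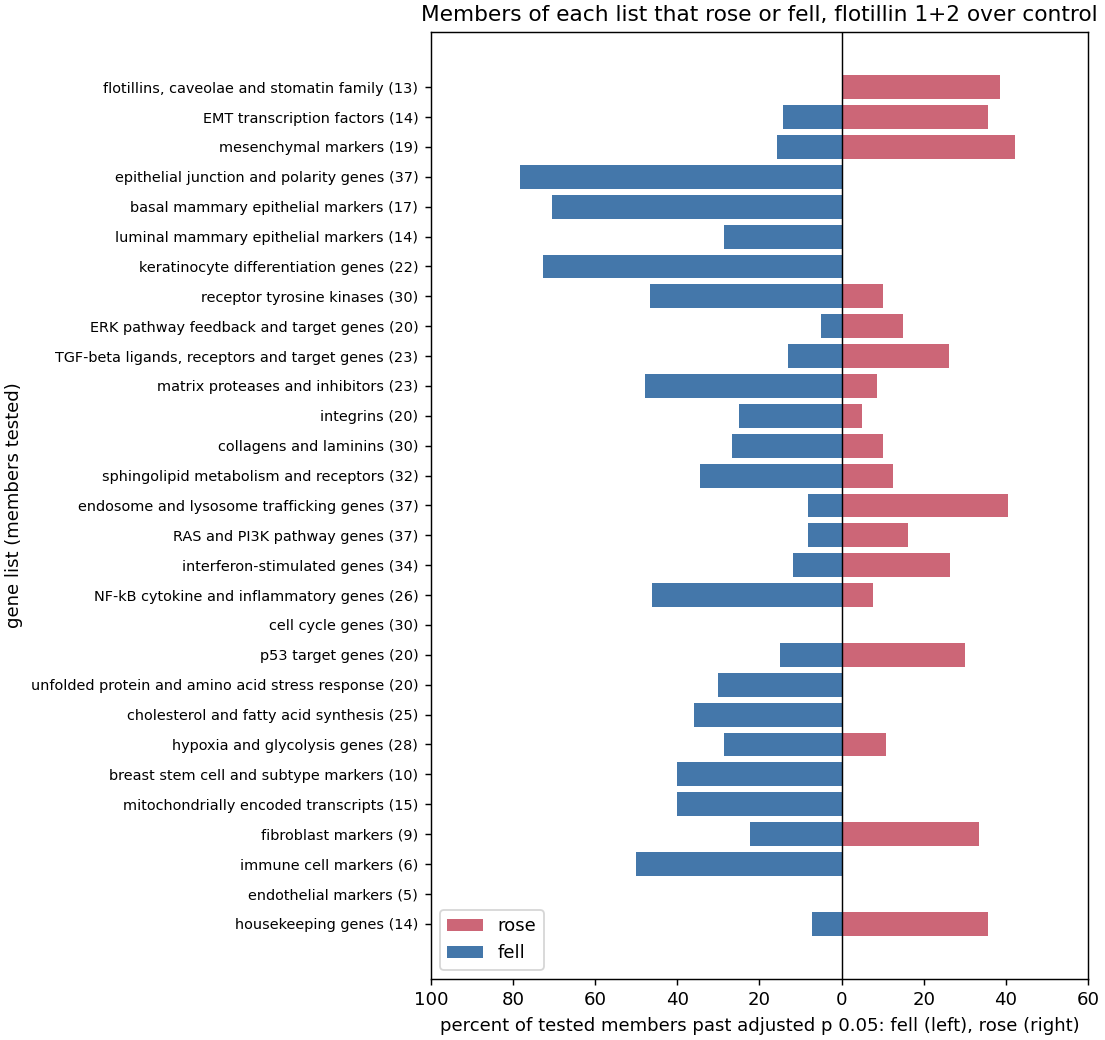
Percent of the tested members of each of 29 gene lists that rose (right of 0) or fell (left of 0) past adjusted p 0.05 in flotillin cells over control, with the number of tested members in brackets. Junction and polarity genes show the highest share of falls, 29 of 37, and the mesenchymal markers the highest share of rises, 8 of 19.

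Matrix and adhesion genes moved in both directions. Of 23 matrix proteases and inhibitors 11 fell and 2 rose (11 and 2 adjusted over the list alone; adjusted p = 0.00419, and adjusted p = 0.335 with an estimated correlation); MMP28 fell 37.2-fold and PLAT, the tissue plasminogen activator gene, 4.17-fold. Integrin genes had 5 falls and 1 rise among 20 (5 and 1 adjusted over the list alone; adjusted p = 0.0272, and adjusted p = 0.684 with an estimated correlation). ITGB6 fell from 2652 ± 502 to 307 ± 108 and ITGA2 from 8222 ± 2056 to 1167 ± 376 normalized counts (SD, n = 3), and ITGA6 fell 7.62-fold. Among 30 collagens and laminins 8 fell and 3 rose (8 and 3 adjusted over the list alone; adjusted p = 0.0154, and adjusted p = 0.81 with an estimated correlation). The limma fit called 3 rises and 3 falls among the collagens and laminins, and their set test had an adjusted p of 0.692 there and 0.124 in the Tuxedo table. LAMA3, a chain of laminin 332, fell 16.1-fold and COL8A1 rose 4.68-fold, though the authors' deposited table from the Tuxedo pipeline gives COL8A1 a q-value of 0.0722. TGF-beta ligands, receptors and targets gave 6 rises and 3 falls among 23 (8 and 3 adjusted over the list alone; adjusted p = 0.039, and adjusted p = 0.684 with an estimated correlation). Beside CTGF, PMEPA1 rose 4.50-fold and the ligand gene TGFB2 3.45-fold. In this list 13 of 21 genes were higher and 4 lower in library 3 of both groups.

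Receptor and signalling genes were lower more often than higher at the receptor level. Of 30 tested receptor tyrosine kinase genes 14 fell and 3 rose (15 and 3 adjusted over the list alone; adjusted p = 8.36e-09, and adjusted p = 0.335 with an estimated correlation). The fibroblast growth factor receptor gene FGFR3 fell from 2477 ± 1700 to 14.3 ± 8.3 normalized counts (SD, n = 3), and FGFR2 fell 16.0-fold. ERK pathway feedback and target genes had 3 rises and 1 fall among 20 (5 and 2 adjusted over the list alone; adjusted p = 0.178), with the cyclin gene CCND1 3.56-fold higher, the phosphatase gene DUSP4 2.25-fold higher and SPRY1 2.33-fold lower. Limma without library 3 of both groups called 8 rises and 3 falls in the ERK list. RAS and PI3K pathway genes had 6 rises and 3 falls among 37 (6 and 3 adjusted over the list alone; adjusted p = 0.496), with RGL1 3.19-fold higher; the list's median log2 fold change was 0.04 and its mean -0.02. The Tuxedo table called 2 rises and 1 fall in the RAS and PI3K list, and limma without library 3 of both groups 7 and 6. With fry on the recovered libraries this list passed upward (adjusted p = 0.0365).

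Among membrane and trafficking genes, 15 of 37 endosome and lysosome genes rose and 3 fell (17 and 4 adjusted over the list alone; adjusted p = 0.0133, and adjusted p = 0.684 with an estimated correlation). The small GTPase gene RAB31 rose 9.89-fold, from 90.6 ± 24.6 to 896 ± 218 normalized counts (SD, n = 3). NPC1, a lysosomal cholesterol transporter gene, fell 2.17-fold. Sphingolipid genes had 11 falls and 4 rises among 32 (11 and 4 adjusted over the list alone; adjusted p = 0.0832, and adjusted p = 0.335 with an estimated correlation). The set test's adjusted p was 0.00901 in the Tuxedo table, 0.0321 with ranks and 0.0383 on the limma fit, but 0.249 with a preset correlation of 0.05, 0.0618 at a mean of at least 100 and 0.0687 in limma without library 3 of both groups. The fry test on the recovered libraries passed downward for the sphingolipid genes (adjusted p = 0.00492). The sphingosine-1-phosphate receptor gene S1PR3 rose 3.66-fold, and SPTLC2, a subunit of the first enzyme of sphingolipid synthesis, fell 3.19-fold. Of 25 cholesterol and fatty acid synthesis genes 9 fell (12 adjusted over the list alone; adjusted p = 0.00972, and adjusted p = 0.684 with an estimated correlation). SCD, a fatty acid desaturase gene, fell 3.30-fold between the authors' means. Of the 23 members with recovered reads, 22 were also higher in library 3 than in the mean of libraries 1 and 2 in both groups. Limma without these libraries called 3 rises and 10 falls, with a set test adjusted p of 0.238.

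Among inflammatory genes, 12 of 26 NF-kB cytokine and inflammatory genes fell and 2 rose (13 and 2 adjusted over the list alone; adjusted p = 0.00025, and adjusted p = 0.519 with an estimated correlation). IL1A fell from 1495 ± 632 to 126 ± 26.9 and IL1B from 477 ± 99.0 to 40.1 ± 27.7 normalized counts (SD, n = 3). The acute phase genes SAA1 and SAA2, near-identical copies whose reads can be shared, fell from 13271 ± 5932 to 1245 ± 945 and from 4937 ± 3119 to 459 ± 362 normalized counts (SD, n = 3). In this list 14 of 22 genes were lower in library 3 of both groups than in the mean of the other libraries. Interferon-stimulated genes had 9 rises and 4 falls among 34 (9 and 4 adjusted over the list alone; adjusted p = 0.156), with IFI44L 3.78-fold and IFI35 3.40-fold higher; the Tuxedo table called 4 rises and 4 falls, and limma without library 3 of both groups 14 and 4. Immune cell markers had 3 falls among 6 tested (3 adjusted over the list alone, cameraPR adjusted p = 0.157). With fry, over 4 members, the adjusted p was 0.0469. The falls included CSF1R (3.87-fold) and CD14, at 743 ± 550 in control and 118 ± 64.7 in flotillin libraries (SD, n = 3).

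Hypoxia and glycolysis genes had 8 falls and 3 rises among 28 (10 and 5 adjusted over the list alone; adjusted p = 0.156); the glucose transporter gene SLC2A1 fell 3.81-fold, VEGFA 2.54-fold and SLC2A3 from 407 ± 306 to 34.8 ± 11.7 normalized counts (SD, n = 3). In this list 20 of 24 genes were higher in library 3 of both groups. Of 20 p53 targets 6 rose and 3 fell (6 and 3 adjusted over the list alone; adjusted p = 0.157), with the cell cycle inhibitor gene CDKN1A 2.89-fold higher. The Tuxedo table called 2 rises and 1 fall here, and 12 of 20 genes were lower in library 3 of both groups, with 0 higher. Unfolded protein and amino acid stress genes had 6 falls among 20 (7 and 2 rises adjusted over the list alone; adjusted p = 0.456), among them the chaperone gene HSPA5 (1.77-fold) and ASNS (1.86-fold). Mitochondrially encoded transcripts had 6 falls among 15 (7 adjusted over the list alone, set test adjusted p = 0.0133), with MT-CO2 2.13-fold lower between the authors' means. The Tuxedo table called 1 fall, but MT-CO2 was not marked as tested there. Its set test covered 8 members and passed downward (cameraPR adjusted p = 0.0173). None of the 15 had recovered reads in both groups and a mean of at least 10, so no estimated correlation was computed. Of 14 housekeeping genes 5 rose and 1 fell (5 and 1 adjusted over the list alone; adjusted p = 0.156), with GAPDH 2.54-fold higher between the authors' means, and 7 of 10 genes were higher in library 3 of both groups.

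Cell cycle genes stood apart in library 3 of each group. In the authors' deposited table, from DESeq2, 0 of 30 tested members passed adjusted p 0.05, with 0 at an unadjusted p under 0.05; the Tuxedo table and the limma fit also called 0. The set test for a rise had an adjusted p of 0.235 in the DESeq2 results, 0.0268 in the Tuxedo table and 0.000839 in limma without library 3 of both groups, and adjusted p = 0.782 with an estimated correlation. Their median normalized count was 354, 708 and 3201 in control libraries 1, 2 and 3, and 1093, 1081 and 4080 in flotillin libraries 1, 2 and 3. All 31 genes were higher in library 3 than in the mean of the other libraries in both groups. Without library 3 of both groups, an alternative chosen after seeing the data, limma called 17 rises and 1 fall in this list. Across 11370 genes with a mean of at least 100, control library 3 correlated with the other control libraries at Pearson r of 0.857 and 0.866 and with flotillin library 3 at 0.832; genes are not independent replicates. Of 5 tested endothelial markers, 0 passed in DESeq2, with 0 at an unadjusted p under 0.05 and 0 in the Tuxedo table and limma (set test adjusted p = 0.625).

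**Figure D3:**
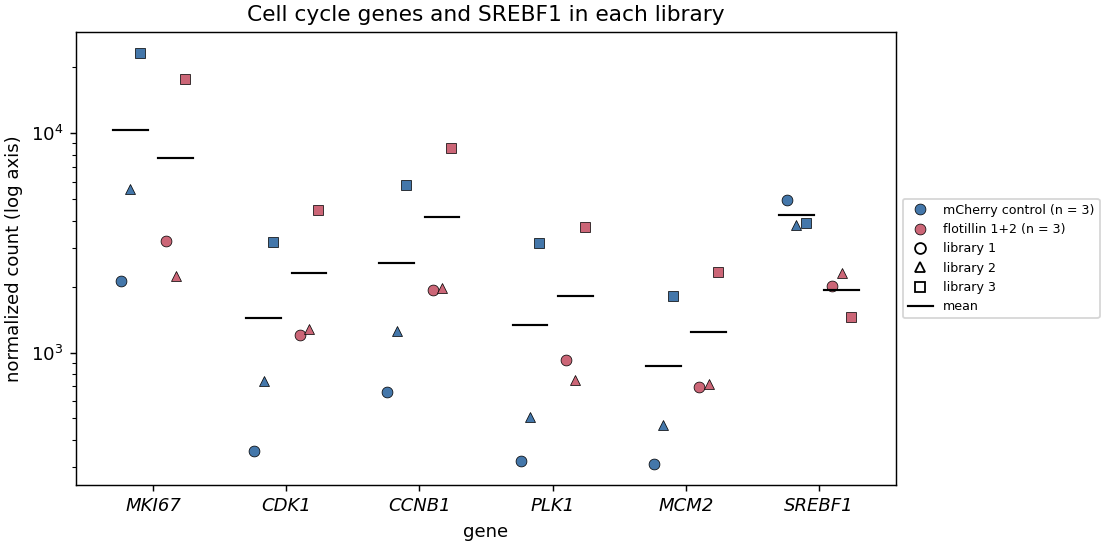
Normalized counts (log axis) of 5 cell cycle genes and SREBF1 in each library, with the group mean as a bar; the cell cycle genes were chosen after their values were seen. Library 3 (squares) is the highest library of its group for each of the 5 cell cycle genes, with MKI67 at 23331 in control and 17633 in flotillin library 3.

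Taken over the lists, 17 of 29 passed the set test, 5 upward and 12 downward, and 16 passed without FLOT1 and FLOT2. With an estimated correlation (limma camera on the recovered libraries) 0 passed. There 3 lists had an unadjusted p under 0.05, and the smallest adjusted p was 0.335. Even junction and polarity genes, with 29 falls and 0 rises among 37, had an unadjusted p of 0.0188 in this camera test. With 3 libraries per group, not passing there does not show that a list did not move. The fry test, which asks whether a list's own genes move one way, passed 13 of the 28 lists it could be run on. By adjusted p, sphingolipid genes (0.00492), RAS and PI3K genes (0.0365) and immune cell markers (0.0469) passed fry but not cameraPR. TGF-beta genes (0.0951), integrins (0.0773), collagens and laminins (0.644), endosome and lysosome genes (0.0915) and cholesterol genes (0.382) passed cameraPR but not fry. In every cameraPR and camera setting other than the estimated correlation, 6 lists kept their call. They were junction and polarity genes, basal markers, keratinocyte differentiation genes, receptor tyrosine kinases, matrix proteases and NF-kB genes. Of these 6, only the NF-kB genes did not pass the fry test (adjusted p = 0.0951). The other 11 lists lost their call in at least 1 setting. Among these, the EMT transcription factors had an adjusted p of 0.12 and luminal markers one of 0.128 in limma without library 3 of both groups. On the limma fit with all libraries it was 0.168 for TGF-beta genes, 0.184 for integrins, 0.0609 for endosome and lysosome genes and 0.0779 for stem cell and subtype markers. Mitochondrial transcripts had 0.0587 and cholesterol genes 0.0686 with a preset correlation of 0.05.

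The authors' 2 pipelines were compared over the 16362 genes tested in both, which describes processing of the same libraries and not replication. Both tables called 1009 genes higher and 1353 lower, and 0 genes in opposite directions. Lists of these sizes would share 160.5 and 227.0 genes if independent. The count-based table alone called 2084 genes, of which 2069 had the same sign in the Tuxedo table, and the Tuxedo table alone called 495. Across genes, the log2 fold changes correlated with a Pearson r of 0.96 and a Spearman rho of 0.978. Among the genes named above, CDH1 has a log2 fold change of -7.98 and FLOT2 one of 4.25 in the authors' deposited table from the Tuxedo pipeline.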

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

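The tests in this part were chosen after the result was seen. RNF6, a ubiquitin ligase gene on chromosome 13, has 0 reads in all 3 flotillin libraries of the count-based table, while the Tuxedo table lists it at 29.6 FPKM in flotillin and 20.9 FPKM in control cells. It stood out because a signal appears in a table outside the main measurement where the main one holds a 0. Its control libraries held 1066, 1381 and 0 normalized counts.

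RNF6 is 1 of 45 genes that have 0 reads in at least 1 library beside at least 500 normalized counts in another library of the same group, among them the cytoskeletal genes FLNA and PLEC and the cathepsin gene CTSB. Low depth is argued against, since the lowest count above 0 beside such a 0 was 211. If the genes were silent in those cells, the Tuxedo ratios would follow the ratios that include the zeros; their median absolute log2 difference from Tuxedo was 0.58 with the zeros and 0.14 without, over 38 genes. For 30 of these 38 genes the ratio lay closer to Tuxedo without the zeros (exact sign test p = 4.72e-04), as reads lost while single libraries were counted would give. The sign test takes genes as independent, which neighbours are not. Of the 45 genes, 12 had another within 1500000 bases at 0 in the same library. In 1000 draws of random genes with a mean of at least 500, the 95th percentile of such neighbours was 8. RNF6 and PLEC were not among the 38 genes compared with Tuxedo. Whether a counting step lost the reads, and which one, stays open.

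In the count-based comparison 0 of the 45 genes passed adjusted p 0.05 in the authors' deposited table from DESeq2, and 7 passed in the one from the Tuxedo pipeline. FAT2, an atypical cadherin gene chosen here after its values were seen, had 15661, 0 and 11981 normalized counts in control and 32.0, 26.4 and 17.5 in flotillin libraries, with an adjusted p of 0.208 in the authors' deposited table. FOXO3 had 0 reads in flotillin library 1 and a log2 fold change of 1.17 in the authors' deposited table from Tuxedo.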

How the results depend on the processing

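The choices named here were fixed before the data were examined except the limma fit, total-count scaling, settings without library 3 or with a term for it, the removal of genes with zeros and the set test without FLOT1 and FLOT2. The 4661 calls became 2885 in the Tuxedo table, 2878 at adjusted p under 0.01, 2815 with an absolute log2 fold change of at least 1, and 920 with Bonferroni adjustment (fewer by construction). Limma gave 3716 with all libraries and 7032 without library 3 of both groups. Other settings gave between 3546 (limma-voom) and 4721 (mean of at least 10). The 2298 rises became 1180 in the Tuxedo table, while limma gave 1944 with all libraries and 3762 without library 3 of both groups. The limma count of 3716 became 7032 without library 3 of both groups and 7318 with a term for it. Leaving out 1 library gave 1723 without control library 1, 1626 without control library 2, 6400 without control library 3, 998 without flotillin library 1, 1136 without flotillin library 2 and 2272 without flotillin library 3; fewer samples lower such counts, and the cause of the rise was not tested. Called lists went from 17 to 11 with a preset correlation of 0.05. On the limma fit 12 lists passed with all libraries, 9 without library 3 of both groups and 0 with an estimated correlation. Genes called by both pipelines in one direction went from 2362 to 1378 at adjusted p under 0.01. AXL turned to -0.18 (log2) without library 3 of both groups, not past the threshold in either case; the cause was not tested. Of 100 named genes in the limma fit, 96 kept direction and call, and between 66 (without flotillin library 1) and 100 (without control library 3) did so with 1 library left out. In the results of Tuxedo, 96 named genes kept their call and 17 lost it in the same direction.

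Of the 10 splits of the 6 recovered libraries into 3 and 3, only 1, the real one, called 3716 genes, and the highest other split called 1; 10 splits are too few for a share under 0.05. No paired analysis was possible because the recovered libraries carry no replicate numbers. This concerns the labels' replicate numbers. Sample numbers in the group names alternate between the groups, but do not identify the recovered libraries. Deviations within groups correlated at a Pearson r of 0.703 for control and flotillin library 3, 0.678 for library 1 and 0.304 for library 2. Control library 1 and flotillin library 2 gave 0.452. A term for library 3, chosen after seeing the data, gave 7318 limma calls against 3716. A block for each pair was not fitted. TMM against size factors and the DESeq2 Wald test on counts were not run. The recovered reads leave out 107 genes with a high mean in 1 or both groups, which limits library-level values for FLOT2, VIM and FN1.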

Other observations

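The 5 gene lists, the genes named and the tests in this part were chosen after the data were seen. Target genes of the growth-control coactivators YAP and TAZ had 8 rises among 25 tested members, with 5 of the 26 also in a list above. In library 3 of both groups 16 of 25 were higher and 3 lower, and limma without these libraries gave 9 rises, 3 falls and a set test adjusted p of 0.117. CYR61 rose from 597 ± 104 to 3078 ± 920 normalized counts (SD, n = 3), and ANKRD1 from 5.54 ± 5.96 to 149 ± 27.8 (SD, n = 3). Neuronal genes gave 4 rises and 1 fall among 13 tested synapse and neurite genes, with the microtubule-associated gene MAP1B higher, from 67.9 ± 32.6 to 1141 ± 798 normalized counts (SD, n = 3). Tight junction genes fell in 14 of 18 tested, 14 of the 20 being in the junction list too, and kallikrein and serpin B genes in 9 of 12, with 2 falls in the Tuxedo table. Complement genes had 2 falls among 18 tested, with C1R at 5208 ± 3939 in control and 1391 ± 617 in flotillin libraries (SD, n = 3), and 12 of 15 were lower in library 3 of both groups.

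Each list was set against the hypothesis that its genes may have moved together in 1 direction. Adjusted p-values of cameraPR over the 5 lists were 0.000138 for YAP and TAZ targets, 0.0005 for synapse and neurite genes, 9.89e-21 for tight junction genes, 1.47e-05 for kallikreins and serpins (0.122 at a mean of at least 100) and 0.315 for complement genes. With an estimated correlation the adjusted p-values were 0.405, 0.373, 0.0953, 0.373 and 0.732 in that order. The lists were written from genes already seen to change, so these tests do not decide the hypotheses.

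Library 3 of each group, the one with the smallest size factor, had cell cycle genes at a median log2 difference of 2.53 in control and 1.97 in flotillin from the mean of the other libraries. Library size is argued against, since library 3 differed by at most 3.4% of reads. An exchange between the groups is argued against by FLOT1, at 1166 normalized counts in control library 3 and 18932 in flotillin library 3. Over 11325 genes, the deviations of the 2 libraries from the others of their group correlated with a Pearson r of 0.703, against 0.678 for control library 1 with flotillin library 1, the highest other pair; deviations within a group are not independent. A growth state or preparation day shared by both libraries may account for this, and these cannot be separated here; no biological explanation from the design was tested.

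A fold change without a p stands in the authors' deposited table for 29 genes. Of these, 15 were highest in flotillin library 3 and 8 in control library 3. POSTN, encoding periostin, had 67.0, 31.4 and 1240 normalized counts in flotillin libraries 1, 2 and 3, and COL6A3 had 432, 115 and 5388.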
